A study of Homo sapiens with 6 samples.

How the data were processed

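RNA was sequenced from 6 libraries of Ishikawa cells, a human endometrial adenocarcinoma line, of which 3 came from parental cells and 3 from derivatives in which the R749Q change had been knocked into XPO1 with CRISPR/Cas9. Per the labels, RNA was reverse transcribed with oligo-dT primers and sequenced as paired ends on an Illumina instrument. The labels number the libraries 1 to 3 in each group and do not say whether they are separate cultures or separate clones, nor whether the library kit kept the strand.

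The data analysed are 1 table of 419 genes that the authors chose as differing between the groups. Per the file headers, it holds for each gene a read count in each library, a TPM value in each library (a share of the library corrected for gene length), and the authors' log2 fold change, p-value and adjusted p-value. The submitters' processing notes name cutadapt, HISAT2, StringTie, DESeq2 and the genome build hg19. The role of each tool, its version and the counting rules are not given in the sources used here. In the authors' deposited table the adjusted p-values reach 0.05 at most and the smallest absolute log2 fold change is 1.07. The ratio of the deposited p-value to its adjusted p-value gave 18087 tests, and the last listed gene had rank 419 among them, so every gene past that adjusted p is in the table.

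The totals of these counts are totals over the listed genes and not library sizes, so the depth of the libraries is unknown. Library scaling was therefore recovered from the authors' deposited log2 fold changes, by least squares of these on the counts over the 159 genes with at least 30 counts in every library. The median absolute residual was 0.0022 on the log2 scale. Counts divided by the recovered factors are called normalized counts. On data simulated with DESeq2 from known factors, over 419 genes, the largest error of a recovered factor was 0.0294 on the log2 scale. A second way, from the TPM per count of 134 genes with at least 50 counts, gave other factors and was added as an alternative after seeing the data. The design had named least squares on the authors' normalized means, or steps of a normalized value per count, where such columns exist. Otherwise it had named TMM scaling over the listed genes, which is among the alternatives below. The table gave no normalized means. The fit to the log2 fold changes, which are ratios of such means, was thus adapted from the first way after the columns were seen.

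Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, 2-sided, 1 term for the group, no filter on low counts), with Benjamini-Hochberg adjustment over the 419 listed genes. A gene was said to rise or fall at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Adjustment over genes already chosen as differing is lenient. The same p-values were therefore also adjusted over all 18087 tests, with every gene outside the table ranked after the listed ones. This is called the wide adjustment below, and for given p-values it cannot give a smaller adjusted p than the full table would. A gene that did not pass it might therefore still pass over the full table. The p-values themselves rest on dispersions estimated over the 419 listed genes, which had been chosen on these libraries. They may differ from those of a full table, and the wide adjustment does not correct for this. Standard errors of log2 fold changes were taken from the fold change and the test statistic. On simulated counts for the comparison of knock-in with parental cells (419 genes), 67% of 100 genes changed by a log2 fold of 1.5 were recovered, 99% of 100 genes changed by a log2 fold of 3, and 1 of 219 unchanged genes was called. The estimated biological coefficient of variation was 0.399, and the simulation gave it to all genes and libraries alike. In the data, knock-in library 3 differed more from knock-in libraries 1 and 2 than these did from each other. The simulated rates may therefore not hold for these data.

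A total of 37 gene lists was fixed, with the test designs and the groups, before the data were examined. The table holds no background of unchanged genes, so no enrichment among expressed genes was tested. For the 8 lists with at least 5 members in the table, the split of members into higher and lower was compared with that of the other listed genes by Fisher's exact test (2-sided), with Benjamini-Hochberg adjustment over the 8 lists. Fewer members were only described. Fisher's exact test takes genes as independent, which related or neighbouring genes may not be. With p-values adjusted over the list alone, the members called in each list were those called over all listed genes.

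The genes named in the text follow a fixed rule that took 98 genes. It takes XPO1, AXL, HIF1A, EPAS1, GAS6 and VEGFA where listed, and the 12 largest rises and 12 largest falls among called genes that carry a gene symbol, do not overlap between the groups, and have a mean normalized count of at least 100 in the higher group. It adds up to 4 members of each list by smallest p, and the 5 called genes with the highest mean. Other members of a list are named where its members are counted. A few genes that the rule or the lists take are not reported here.

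Where all libraries of a group had 0 counts, the fold is a lower limit computed against a floor of 3 counts over the group. The floor rests on fewer reads when a library is left out, which divides a limit by 3.35 without knock-in library 3 and by 1.11 to 1.6 without another library of the group at 0. Intervals and floors cover counting error only, since PCR copies of a read are not independent molecules. The alternatives were the replicate number as a block, DESeq2 1.42.0, scaling by TMM, by median of ratios or by the total over the listed genes, 2 filters on low counts, each library left out, robust dispersion, a test against a log2 fold change of 1, and the 2 alternatives added after seeing the data (TPM-based scaling and the wide adjustment).

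The deposited table pairs 374 of the gene identifiers with symbols. Another 24 symbols came from a table of gene names, and 21 identifiers had none. GENCODE release 29 (assembly GRCh38) held 411 of the identifiers (98.1%). It was used for chromosome membership, the order of genes and exon length, and no coordinates are given, since the build of the deposited values is hg19. Summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.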

Results

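The transcriptomes of Ishikawa endometrial cancer cells and of their XPO1 R749Q knock-in derivatives were compared, with 3 libraries in each group. XPO1 is the receptor that carries many proteins out of the nucleus. The series asks what the R749Q change does in endometrial cancer cells, and its title points to HIF, AXL, PI3K and MAPK signalling. Values are given for 419 genes that the authors chose as differing. The listed genes held 310073, 332393 and 267785 counts in parental libraries 1 to 3, and 320969, 155105 and 1133520 counts in knock-in libraries 1 to 3. These genes made up 0.699% to 0.763% of the TPM of the parental libraries, and 1.13%, 1.38% and 2.78% of that of knock-in libraries 1, 2 and 3. Nothing in the labels says that the 3 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

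Most of the listed cancer-testis genes fell in knock-in cells, whereas most of the other listed genes rose. PAGE2, a cancer-testis gene, fell from 10789 ± 915 to 2.68 ± 2.58 normalized counts (mean ± SD, n = 3 per group), and MAGEC2 fell from 11037 ± 961 to 194 ± 75.5. TGM2, which encodes a protein-crosslinking transglutaminase, rose from 90.0 ± 11.7 to 3143 ± 897, and the haptoglobin gene HP rose from 25.1 ± 7.33 to 1278 ± 231. AXL (ENSG00000167601.12_4), a receptor tyrosine kinase gene, had 0 counts in all 3 parental libraries and a mean of 61.9 ± 27.2 normalized counts in knock-in cells. EPAS1 (ENSG00000116016.14_6), which encodes a HIF alpha subunit, rose from 26.9 ± 7.28 to 248 ± 64.2.

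Of the 419 listed genes, 240 rose and 178 fell in knock-in cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The groups did not overlap in 411 genes, where chance gives 10% for 3 libraries against 3, but the genes had been chosen on these libraries for differing. The 1 gene that did not pass was the pseudogene RPL19P16, whose 181 normalized counts in knock-in library 2 stood against 0 in the other libraries (adjusted p = 0.0674), while the authors' deposited table gives it an adjusted p of 5.4e-06. With the wide adjustment over all 18087 tests, 106 genes passed, of which 58 rose and 48 fell, and 54 of the 98 named genes no longer did. Scaling by the median of ratios over the listed genes left 117 rising and 178 falling genes, since it centres on genes that had been chosen as changed. Among the 98 named genes it ended the calls of CCN1, CDKN1C, DDIT3, DKK3, DUSP5, FBLN1, ID2, IFIT2, ITGA2, ITGA3, LTBP2, MT-TA, MT-TY, PGF, SLC1A3 and TOP2A and gave NDUFB8, S100A11 and TNC the other sign, while TPM-based scaling ended the calls of BST2, ITGB3, JAG2, MSX1 and SPRY1. Among the other list members given by symbol, median-of-ratios scaling ended the calls of CLDN1, CXCL1, FZD5, KRT7, KRT17, KRT80, LAMA3, SAA1, SLC20A1 and TGFBI, and TPM-based scaling that of PRAME.

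**Figure D1:**
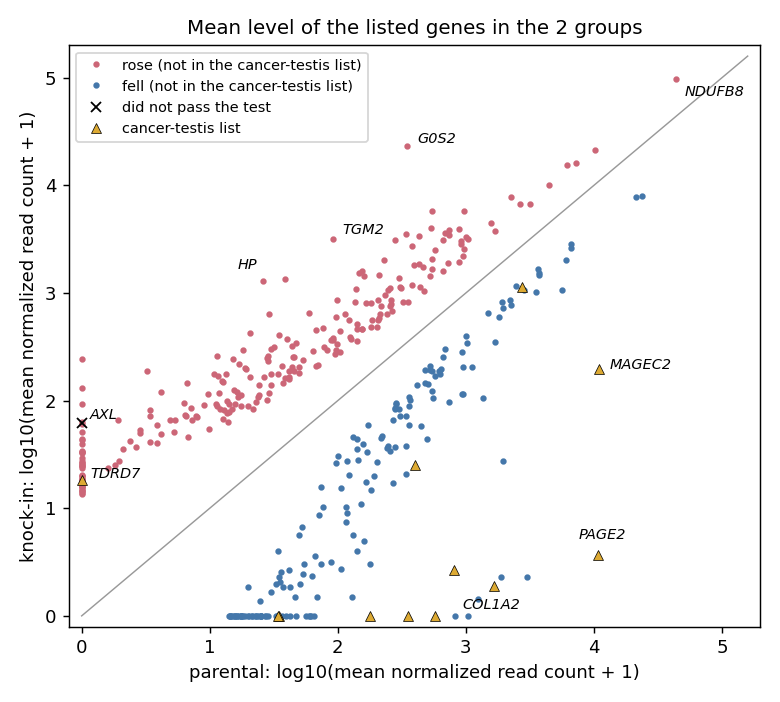
Mean normalized read count of each listed gene in parental (x axis) and knock-in libraries (y axis), both as log10(mean + 1), with 3 libraries per group and the line of equal means in grey. Red and blue points are the 240 genes that rose and the 178 that fell, apart from members of the cancer-testis list (yellow triangles). Of these members, 11 lie below the line and TDRD7 lies above it. The cross is RPL19P16, which covers the point of AXL.

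The signalling named in the title was examined first, from the lists of its components. Of the 10 names in the list of HIF pathway components, EPAS1 alone was in the table (edgeR, log2 fold change 3.19 ± 0.38 SE, adjusted p = 0.000471). It passed the wide adjustment (adjusted p = 0.0204). Its normalized counts were 174, 282 and 287 in the knock-in libraries and 19.0 to 33.3 in the parental ones. Of the 46 names in the HIF target list, 2 were in the table and both rose. These were the chemokine receptor gene CXCR4, from 12.7 ± 6.33 to 98.3 ± 30.4, and the placental growth factor gene PGF, from 43.4 ± 27.4 to 255 ± 22.6, although neither passed the wide adjustment (adjusted p = 0.0631 and 0.148). XPO1, HIF1A, GAS6 and VEGFA were not among the listed genes. The HIF lists were fixed beforehand and may leave out other HIF-related genes of the table.

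Of the receptor tyrosine kinases and their ligands, 5 were listed, of which AXL, RET, HBEGF and FGF1 rose and EPHB3 fell, a split that did not differ from that of the other listed genes (Fisher's exact test, 2-sided, adjusted p = 0.634). AXL was at least 65.8-fold higher in knock-in cells (edgeR, adjusted p = 0.00102, and 0.0442 with the wide adjustment), with 43.7, 93.2 and 48.9 normalized counts in knock-in libraries 1 to 3, and this limit was 43.2-fold and 41.0-fold without parental libraries 1 and 2. RET, the receptor for glial-derived neurotrophic factors, rose from a mean of 14.5 to 125 normalized counts (log2 fold change 3.11 ± 0.38 SE). The EGF receptor ligand gene HBEGF rose from 17.8 ± 7.22 to 201 ± 149, a log2 fold change of 3.50 that was 2.69 without knock-in library 3 and 4.19 with TPM-based scaling. EPHB3 fell from 933 ± 94.5 to 280 ± 152. Of the PI3K-AKT list, INPP4B, a phosphoinositide phosphatase gene, rose from 30.7 ± 12.1 to 311 ± 224, a log2 fold change of 3.35 that was 2.56 without knock-in library 3 and 4.04 with TPM-based scaling, and AKT1 fell from 524 ± 121 to 189 ± 39.7. Of the MAPK output list, the ERK phosphatase gene DUSP5 rose from 21.9 ± 4.95 to 95.9 ± 44.7, and the feedback inhibitor gene SPRY1 fell from 6598 ± 770 to 2843 ± 497. Within this group, AXL and RET (adjusted p = 0.023) passed the wide adjustment, whereas HBEGF, FGF1, INPP4B, AKT1, DUSP5 and SPRY1 did not.

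The listed cancer-testis genes, which are normally expressed in germ cells and in some tumours, mostly fell. Of 12 members, 11 fell, 10 of them on the X chromosome, and 1 rose, so that 8.3% were higher in knock-in cells against 59.0% of the other listed genes (Fisher's exact test, 2-sided, p = 0.000508, adjusted p = 0.00406 over 8 lists). This was the 1 list of the 8 tested whose split differed from that of the other genes. Fisher's exact test takes genes as independent, and many of these members are related to one another, so its p-values may be too small. MAGEC1 was at least 459.5-fold lower, PAGE5 at least 234-fold lower and XAGE1A at least 758-fold lower, with 0 counts in every knock-in library. Without knock-in library 3, which holds most of the reads behind such a 0, these limits were 137-fold, 69.8-fold and 226-fold. XAGE1B fell from 1646 ± 230 to 0.911 ± 0.793, and MAGEB2 fell from 807 ± 63.1 to 1.69 ± 2.93, with its 14 knock-in reads in library 3 alone. MAGEA1 fell from 399 ± 34.2 to 24.4 ± 12.8, MAGEA9 and MAGEB1 had 0 counts in knock-in cells, and PRAME fell from 2729 ± 186 to 1132 ± 257. TDRD7, a germ granule gene, was the member that rose, to 17.3 ± 3.88 from 0 counts. The list was made partly from the first letters of gene symbols, so it may take genes of other kinds. It misses the cancer-testis genes CT55, which fell (log2 fold change -2.88), and DSCR8, which rose (10.27), and may miss others. XAGE1A, XAGE1B, PAGE2, PAGE5 and the MAGE genes belong to families of similar genes, some of them near-identical. The division of reads among them is therefore uncertain.

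Among the other genes with the largest falls, the collagen gene COL1A2 went from 824 ± 53.6 normalized counts to 0 (at least 1081-fold lower) and TCL1B, a lymphoid and germ cell oncogene, from 1043 ± 89.1 to 0 (at least 1369-fold lower). Without knock-in library 3 these limits were 322-fold and 408-fold. GTSF1, a factor of the piRNA pathway of germ cells, fell from 1937 ± 107 to 26.3 ± 20.4, a log2 fold change of -6.11 that was -7.18 without knock-in library 3. PLSCR3 fell from 158 ± 44.7 to 3.93 ± 3.60, whereas the readthrough gene TMEM256-PLSCR3, which overlaps it, was at 0 in parental cells and at 242 ± 55.6 in knock-in cells, so reads of this locus cannot be assigned with certainty. PLSCR3 had a log2 fold change of -5.95, which was -6.77 without knock-in library 2 and -4.88 without knock-in library 3. NICN1 fell by 5.99 on the log2 scale, with values of -8.25 without knock-in library 1 and -4.78 without knock-in library 3.

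The largest rises included G0S2, an inhibitor of lipolysis, which went from 345 ± 22.8 to 23226 ± 13083 normalized counts, with 30562, 30995 and 8121 in knock-in libraries 1 to 3. ABLIM1, an actin-binding protein gene, rose from 37.8 ± 5.03 to 1348 ± 370 (log2 fold change 5.16 ± 0.32 SE, adjusted p = 3.48e-05), and TGM2 and HP rose by 5.12 ± 0.31 and 5.68 ± 0.35 on the same scale. Reads of HP can be shared with its paralog HPR, which also rose. The drug efflux pump gene ABCB1 rose from 19.7 ± 10.5 to 423 ± 213, and the non-coding DSCR8 was at least 137-fold higher, with 86.2, 116 and 185 normalized counts in the knock-in libraries and limits of 90.0-fold and 85.5-fold without parental libraries 1 and 2. MGAT2, NT5E and TUBA8 rose by 5.29, 4.68 and 4.54 on the log2 scale from parental means of 3.15, 5.67 and 10.4. Leaving out single parental libraries moved MGAT2 to between 4.66 and 6.39 and NT5E to between 4.08 and 5.53, and TUBA8 was at 6.94 without parental library 2. Of the genes with the largest changes either way, IL1B, MGAT2, NT5E, TUBA8 and NICN1 did not pass the wide adjustment.

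**Figure D2:**
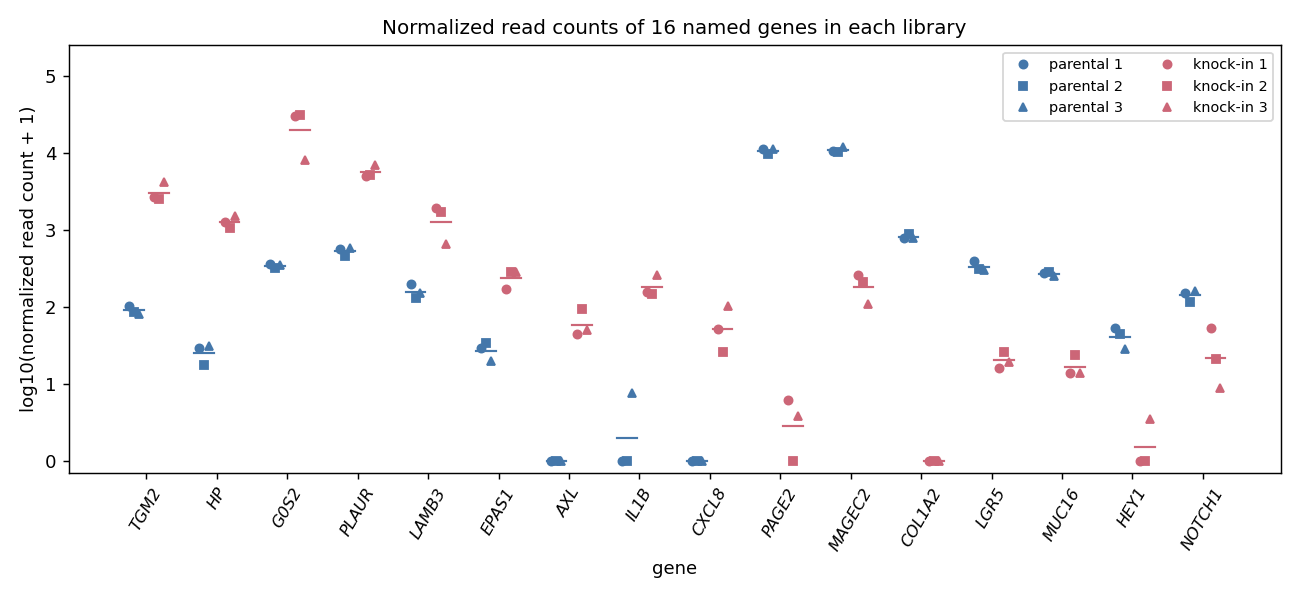
Normalized read counts of 16 named genes on the scale log10(count + 1), with 1 point per library (blue, parental; red, knock-in; symbols give the library number) and a bar at the mean of the 3 values of each group. AXL and CXCL8 were at 0 in every parental library and COL1A2 in every knock-in library, and knock-in library 3 held the lowest G0S2 value of its group, 8121.

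Of 9 listed inflammatory genes, 7 rose (CXCL1, CXCL3, CXCL8, IL1B, IL32, LCN2 and SAA1) and PTGS2 and TNFAIP2 fell, a split that did not differ from that of the other listed genes (Fisher's exact test, 2-sided, adjusted p = 0.634). The neutrophil chemokine gene CXCL8 was at least 63.3-fold higher, with 51.5, 25.2 and 102 normalized counts in knock-in libraries 1 to 3. This limit was 40.7-fold without knock-in library 3, and 41.6-fold and 39.5-fold without parental libraries 1 and 2. The iron-binding lipocalin gene LCN2 rose from 144 ± 10.4 to 1526 ± 649 (log2 fold change 3.40 ± 0.39 SE, adjusted p = 0.000434). IL1B rose from 2.24 ± 3.87 to 187 ± 62.1, a log2 fold change of 6.50 that was 5.90 and 5.85 without parental libraries 1 and 2, while without parental library 3, which held its 6 parental reads, it was at least 142.6-fold higher. PTGS2, the inducible cyclooxygenase gene, went from a mean of 19.4 to 0 (at least 25.4-fold lower, and 7.58-fold without knock-in library 3). LCN2 passed the wide adjustment (adjusted p = 0.0187), and CXCL3, CXCL8 and IL1B did not.

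Of 4 listed interferon-stimulated genes, IFI27 and the neighbours IFIT1 and IFIT2 on chromosome 10 rose and BST2 fell. IFI27 rose from 11.5 ± 1.76 to 151 ± 4.24. IFIT1 had 412, 335 and 1173 normalized counts in knock-in libraries 1 to 3, and IFIT2 had 576, 806 and 2779, against parental means of 112 ± 11.1 and 297 ± 81.6. Their log2 fold changes of 2.52 and 2.23 were 1.74 and 1.21 without knock-in library 3, and 3.235 and 2.997 with TPM-based scaling. BST2, which encodes tetherin, fell from 478 ± 65.8 to 192 ± 45.7. IFI27 passed the wide adjustment (edgeR, adjusted p = 0.00822), and the other 3 did not.

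Most listed genes of the extracellular matrix and its proteases rose. Of 9 listed members, 7 rose, among them FBLN1, LAMA3, LAMB3, PLAT, PLAU and PLAUR, and the collagen genes COL12A1 and COL1A2 fell (Fisher's exact test, 2-sided, adjusted p = 0.634). The urokinase receptor gene PLAUR rose from 541 ± 64.5 to 5740 ± 1116, with a log2 fold change of 3.41 ± 0.24 (SE; edgeR adjusted p = 5.61e-05), and its ligand gene PLAU rose from 153 ± 41.1 to 1597 ± 1075. LAMB3, a laminin beta chain gene, rose from 160 ± 37.1 to 1428 ± 676. The fibulin gene FBLN1 rose from 256 ± 19.9 to 1120 ± 434. PLAUR and LAMB3 passed the wide adjustment (adjusted p = 0.00242 and 0.039), and FBLN1 did not (adjusted p = 0.0525). Both listed adhesion receptors, the integrin genes ITGA2 and ITGA3, rose, by 1.43 ± 0.27 and 1.78 ± 0.42 on the log2 scale (SE), although neither passed the wide adjustment. Both calls ended with median-of-ratios scaling (0.08 and 0.45), and that of ITGA2 also with TMM (0.89) and total-count scaling (0.93). Of the fibroblast markers, COL1A2 and THY1 were listed and both fell, and the leukocyte marker LAPTM5 was at 13.7 ± 8.65 in knock-in cells and 0 in parental cells.

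The listed epithelial and mesenchymal genes went in both directions. Of 8 listed epithelial genes, 6 rose (CLDN1, KRT7, KRT15, KRT17, KRT80 and KRT81) and 2 fell, MUC16 among them (Fisher's exact test, 2-sided, adjusted p = 0.634). The rises of CLDN1 and KRT7, 1.41 and 1.395 on the log2 scale, fell short of the fold threshold with TMM (0.871 and 0.859), total-count (0.909 and 0.894) and median-of-ratios scaling (0.067 and 0.03). MUC16, which encodes the tumour antigen CA125, fell from 270 ± 16.2 to 16.2 ± 5.61 (edgeR, log2 fold change -4.13 ± 0.35 SE, adjusted p = 0.000133). KRT15 and KRT81 were at 0 in parental cells and at 23.7 ± 14.9 and 17.8 ± 11.9 in knock-in cells. Of 6 listed mesenchymal genes, ITGB3, PRRX2, S100A4 and THY1 fell and TGFBI and TNC rose (Fisher's exact test, 2-sided, adjusted p = 0.634), but the rise of TNC, 1.14 on the log2 scale, became -0.21 with median-of-ratios scaling. ITGB3 fell from 508 ± 92.1 to 142 ± 36.6 and S100A4 from 610 ± 82.9 to 187 ± 41.8. With the wide adjustment MUC16 passed (adjusted p = 0.00576), and KRT15, KRT81, ITGB3, PRRX2, S100A4, THY1 and TNC did not.

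All 4 listed genes of the NOTCH pathway fell. The receptor gene NOTCH1 fell from 144 ± 24.9 to 27.0 ± 23.2, a log2 fold change of -2.45 that was -3.55 without knock-in library 1. The ligand genes DLL3 and JAG2 fell from 367 ± 16.6 to 99.6 ± 32.1 and from 100 ± 13.6 to 29.4 ± 4.40, and the target gene HEY1 fell from 41.4 ± 12.3 to 0.845 ± 1.46, with its 7 knock-in reads in library 3. None of the 4 passed the wide adjustment, with adjusted p-values of 0.349 for NOTCH1, 0.0521 for DLL3, 0.0952 for JAG2 and 0.0737 for HEY1. Of 5 listed WNT genes, DKK3, FZD5 and WNT5B rose and LGR5 and WNT7A fell (Fisher's exact test, 2-sided, adjusted p = 1). LGR5, a stem cell receptor, fell from 338 ± 50.6 to 19.7 ± 4.99 (edgeR, log2 fold change -4.13 ± 0.33 SE, adjusted p = 0.000109), and WNT7A, a ligand of the uterine epithelium, was at least 60.2-fold lower, or 17.97-fold without knock-in library 3. LGR5 and ABCB1 were the 2 listed members of the stem cell and drug resistance list and moved in opposite directions. Of 4 TGF-beta and BMP genes, CCN1, ID2 and LTBP2 rose and ID3 fell, with CCN1 going from 52.0 ± 3.30 to 239 ± 77.1 and ID3 from 246 ± 18.6 to 36.6 ± 10.2. LGR5, WNT7A, CCN1 and ID3 passed the wide adjustment, and DKK3, WNT5B, ID2 and LTBP2 did not.

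Of 4 listed hormone-response genes of the endometrium, TFF3 rose and ALPG, IGFBP3 and MSX1 fell. IGFBP3, which binds insulin-like growth factors, fell from 737 ± 287 to 96.9 ± 33.3, and MSX1, a homeobox gene of the uterine epithelium, fell from 479 ± 101 to 145.5 ± 27.5. TFF3 rose from 12.3 ± 10.7 to 177 ± 35.2, a log2 fold change of 3.83 that was 4.83 without parental library 1. Both listed cholesterol genes, INSIG1 and PMVK, fell, from 359 ± 61.0 to 87.3 ± 26.3 and from 1013 ± 198 to 341 ± 141. Both listed cell cycle genes rose in the test over all libraries. TOP2A, the replicative topoisomerase gene, went from 1042 ± 182 to 3186 ± 1749, and CDKN1C, a cyclin-dependent kinase inhibitor gene, went from 257 ± 27.0 to 783 ± 472. The log2 fold change of CDKN1C was 1.61, and 0.99 without knock-in library 3, where it no longer reached the fold threshold, and 2.29 with TPM-based scaling. The stress transcription factor gene DDIT3, the 1 listed gene of the unfolded protein and amino acid responses, rose from 459 ± 33.9 to 1758 ± 341 (edgeR, adjusted p = 0.000466). IGFBP3 and DDIT3 passed the wide adjustment (adjusted p = 0.0334 and 0.0201), and TFF3, ALPG, MSX1, INSIG1, PMVK, TOP2A and CDKN1C did not.

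The metallothionein genes MT1X and MT2A, which bind zinc and copper, rose from 431 ± 43.7 to 3355 ± 1676 and from 339 ± 32.6 to 3491 ± 2170. The pseudogene MT1L, which resembles them, rose from 28.2 ± 6.11 to 641 ± 372, and reads may be shared among the 3. Of 5 listed solute carriers, SLC1A3 and SLC20A1 rose and SLC35E4, SLC39A4 and SLC9A3 fell (Fisher's exact test, 2-sided, adjusted p = 0.748), although SLC20A1 changed sign with median-of-ratios scaling. SLC9A3, a sodium-proton exchanger gene, fell from 1700 ± 277 to 352 ± 109, and the glutamate transporter gene SLC1A3 rose from 90.5 ± 19.6 to 381 ± 67.8. Of the genes whose symbols begin as zinc fingers, ZNF114 rose and ZNF707 and the antisense ZFPM2-AS1 fell. The mitochondrial tRNA genes MT-TA, MT-TC, MT-TN and MT-TY, which lie side by side, rose by 2.13 to 2.39 on the log2 scale, and since they are neighbours and strand is not stated they may count the same transcripts. MT1L, MT1X, SLC9A3, SLC1A3, ZNF114 and the 4 tRNA genes passed the wide adjustment, and MT2A, SLC35E4, SLC39A4, ZNF707 and ZFPM2-AS1 did not.

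The 5 called genes with the highest mean were NDUFB8, RPL36A, G0S2, APEX1 and S100A11. NDUFB8, a subunit gene of respiratory complex I, went from 43641 ± 8846 to 98066 ± 8471, and S100A11, a calcium-binding protein gene, from 10194 ± 866 to 21469 ± 1324, but with median-of-ratios scaling their log2 fold changes of 1.17 and 1.07 became -0.19 and -0.28. APEX1, a DNA repair endonuclease gene, fell from 21106 ± 942 to 7708 ± 2337. Of these 5, G0S2 passed the wide adjustment and the other 4 did not. Among genes whose symbols begin as ribosomal proteins, RPL36A fell from 23829 ± 1440 to 8023 ± 3508 and RPL39L from 930 ± 104 to 115 ± 25.4, while the pseudogene RPLP0P3 rose and RPL19P16 did not pass. Reads of these genes can be shared with processed copies. The remaining 10 lists had no member in the table. They were nuclear export and import machinery, p53 targets, antigen presentation, NRF2 targets, HOX genes, histones, protocadherins, small nuclear and ribosomal RNAs, endothelial markers and neural markers.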

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

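Of the tests in this part, the check of the TPM values and the other splits were planned before their results were seen, and the checks of gene length, of the residual and of the differences within the knock-in group were chosen afterwards.

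Knock-in library 3 stood apart in the TPM values, which the comparison as reported did not use. Its scaling from the authors' log2 fold changes lay above its scaling from TPM per count by 0.963 on the log2 scale, against -0.398 to -0.005 in the other 5 libraries, and the listed genes took 2.78% of its TPM against 1.13% and 1.38% in knock-in libraries 1 and 2. The tables argue against a wrongly recovered factor, since the authors' fold changes were met with a median absolute residual of 0.0022, and against TPM made with other gene lengths, since the interquartile range of log2 count per TPM was 0.0533 in this library and 0.0388 to 0.0603 in the others. They also argue against a loss of short transcripts as the whole cause: the shift of 153 genes of 3000 or more bases exceeded that of 15 genes under 1000 bases by 0.107 (95% interval -0.341 to 0.596), below the gap. What stays open is that genes outside the table, such as a few very abundant ones, may make up a different share of this library, which was not tested here, and no biological explanation was tested. Within the knock-in group, 60 of 184 rising genes with at least 20 counts differed by 2-fold or more between library 3 and the mean of libraries 1 and 2, against 6 between libraries 1 and 2, and of 58 falling genes 8 did, against 2. The median log2 ratio of library 3 to that mean was 0.169 in rising and -0.32 in falling genes. These values depend on the scaling: with TPM-based scaling the counts were 125 and 11 in rising and 27 and 4 in falling genes, and the medians 1.398 and 0.934.

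Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, namely the real one itself, with 418 genes, and the highest of the others gave 0 genes by edgeR. With 10 splits no share under 0.05 can be reached. The genes had also been chosen for differing between the real groups. A high count for the real split and low counts for mixed ones were thus set in advance, so no conclusion is drawn from them.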

How the results depend on the processing

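Of the settings in this part, TPM-based scaling and the wide adjustment were chosen after seeing the data. The fit behind the main scaling was adapted after the deposited columns were seen. The 418 calls (240 rose, 178 fell) became 106 (58 and 48) with the wide adjustment, by its construction. Over the 295 genes with a mean count of at least 50, all were called, with 188 rising and 107 falling, since fewer genes were tested. Median-of-ratios scaling left 295 calls, with 117 rising (39.7% against 57.4%), shifted the median log2 fold change by -1.34 and gave 16 genes the other sign, among the named ones NDUFB8 (-0.19), S100A11 (-0.28) and TNC (-0.21). TMM, total-count and TPM-based scaling shifted the median by -0.54, -0.50 and 0.37 and left 390, 393 and 393 calls. DESeq2 called 419 genes, robust dispersion 418, a test against a log2 fold change of 1 gave 392, and filterByExpr called all 383 genes it kept. Leaving out single libraries gave 407 to 418 calls, 230 to 240 rising and 177 to 178 falling, and the call of CDKN1C ended without knock-in library 3 (log2 fold change 0.99).

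With the replicate number as a block, 349 genes were called (205 rose, 144 fell). Libraries of the same number deviated from their group means with correlations of 0.084, 0.039 and 0.078 across genes, so the numbers were not taken as pairs. Of the 98 named genes, 88 kept their call or its absence with the block, and those that no longer passed were ALPG, KRT15, KRT81, LAPTM5, PRRX2, RPLP0P3, SLC35E4, WNT5B and ZNF707.

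Among the 98 named genes, the call or its absence was kept in 97 with DESeq2, 94 with TMM, 79 with median of ratios, 93 with TPM-based scaling, 93 in the test against a log2 fold change of 1 and 44 with the wide adjustment. RPL19P16 passed with DESeq2, with the block, and without knock-in library 1 or 3. The 1 list that differed, cancer-testis genes, did so under each alternative run for it, with adjusted p between 0.000348 and 0.0141 by Fisher's exact test. This test uses only the direction of each gene. Directions were the same for all 419 genes with TMM, with TPM-based scaling and without any single library other than knock-in library 2. Those settings could thus not change the result. Depth sets a limit for genes with 0 counts in a group, 51 in knock-in and 41 in parental cells, where only a lower limit of the fold can be given.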

Other observations

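The genes and gene families in this part, and the tests of chromosomes, were chosen after their values were seen.

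IL1R2, the interleukin 1 decoy receptor gene, went from 136 ± 30.6 to 821 ± 152 normalized counts (mean ± SD, n = 3 per group), and the receptor antagonist gene IL1RN from 14.8 ± 5.71 to 91.0 ± 13.5. The antiprotease genes SLPI and PI3 rose from 281 ± 29.1 to 3081 ± 1599 and from 15.8 ± 6.22 to 220 ± 59.7. IL1R2, SLPI and PI3 passed the wide adjustment (edgeR, adjusted p = 0.0163, 0.0337 and 0.0163), and IL1RN did not (adjusted p = 0.0639). LAMC3, a laminin gamma chain gene, rose from 16.4 ± 2.91 to 87.2 ± 27.3, a call that ended with median-of-ratios scaling.

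Mucin genes divided, with MUC2, a mucin of intestinal goblet cells, going from 35.5 ± 8.25 to 209 ± 105 (a call that also ended with median-of-ratios scaling), while MUC4 went from 26.4 ± 13.5 to 0 counts (at least 34.7-fold lower, or 10.3-fold without knock-in library 3) and MUC16 fell. The S100 genes divided as well, with S100A2 rising from 254 ± 32.9 to 750 ± 52.4 and S100A14 from 718 ± 33.3 to 1880 ± 688, while S100A4 fell. With median-of-ratios scaling the rises of S100A2 and S100A14 shrank to 0.22 and 0.05 on the log2 scale and that of S100A11 turned to -0.28.

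Listed genes on chromosome 10 were mostly higher in knock-in cells: 30 of 35 were higher (85.7%), against 54.8% of the other listed genes (Fisher's exact test, 2-sided, p = 0.000278, adjusted p = 0.00292 over 21 chromosomes). One gain of the whole chromosome is argued against as the sole cause, since 19 of the 29 risers that passed the test rose by more than 4-fold. This count is smaller with TMM and median-of-ratios scaling. CELF2 and IFIT1, for example, dropped under 4-fold with TMM (1.954 and 1.948 on the log2 scale). ABLIM1 stayed above it with both (4.611 and 3.795). A gain as part of the cause stays open: the median rise was 2.226 on the log2 scale against 2.882 in other risers, and the table, whose smallest change is 1.07, leaves out the smaller rises that a gain would give. Whether knock-in library 3 held extra dosage stays open: its values exceeded those of knock-in libraries 1 and 2 by a median of 0.639 on the log2 scale in 23 chromosome 10 risers and by 0.101 in 155 other risers, a difference of 0.538 (p = 0.037 in a 2-sided permutation test that takes genes as independent, and 0.15 over 178 rotations of the values along the genome, which keep neighbours together). Both p-values cover the spread between genes of these libraries and not between cultures. The neighbours IFIT2, IFIT1 and KIF20B, with excesses of 2.01, 1.65 and 2.48, and SEC23IP and BCCIP, with 2.04 and 1.47, stood highest among them together with ARHGAP19 at 1.66, while PLAU at -2.54 and TLL2 at -1.62 stood lowest. All these values rest on the scaling of library 3, since TPM-based scaling moved the median of all rising genes from 0.169 to 1.398, so their signs decide nothing. The table holds changed genes alone, so the unchanged genes of the chromosome that would show a gain were not analysed here.

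Listed genes on the X chromosome mostly fell: 23 of 27 were lower in knock-in cells, so that 14.8% were higher against 60.5% of the other listed genes (Fisher's exact test, 2-sided, adjusted p = 6.87e-05 over 21 chromosomes). The cancer-testis list held 10 of the 23, and outside it 13 of 17 X-linked genes were lower (Fisher's exact test, 2-sided, p = 0.00408), such as ZMYM3, from 221 ± 12.4 to 46.0 ± 10.7, and TSPAN7, from 95.4 ± 7.82 to 25.1 ± 0.631. The list misses the X-linked cancer-testis gene CT55, which fell (log2 fold change -2.88), and may miss others. These 17 are therefore not free of cancer-testis genes. Loss of 1 X copy as the sole cause of the listed falls is argued against by 18 X-linked genes that fell by more than 4-fold. The table leaves out changes under 1.07 on the log2 scale, and with them smaller falls that such a loss would give. Large falls were thus favoured in advance, and the 18 say nothing of X-linked genes outside the table. Loss of every copy as the sole cause is argued against by 5 listed genes that fell by at most 4-fold. X-linked reads in knock-in cells also argue against loss of every copy in all of these cells, which would leave none under any scaling. ZMYM3 and TSPAN7 kept means of 46.0 and 25.1 normalized counts there, and 4 X-linked genes were higher. The 5 are TSPAN7, SPIN2B, NBDY, HNRNPH2 and RPL36A, and their count depends on the scaling. With median-of-ratios scaling all of them fell by more than 4-fold (-2.46 to -3.28 on the log2 scale). With TMM, TSPAN7, SPIN2B and RPL36A did (-2.46, -2.12 and -2.09). A loss as part of the cause was not tested. The design does not separate an effect of the R749Q change from differences that arose when the knock-in cells were derived.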
